A study of Homo sapiens with 4 samples.

How the data were processed

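Single-cell RNA sequencing data of 4 libraries of vascularised brain organoids from the human line H9 were used, 2 per group. Per the labels' protocols, embryoid bodies received bFGF and VEGF with SB431542 (BMPi) or with BMP4 (BMPa) for 2 days at the vascular step, organoids were dissociated with trypsin for 20 minutes at day 32, 10000 to 12000 cells were loaded, and libraries were sequenced on a HiSeq X. The groups and replicate numbers are those of the labels, which give no day or batch.

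The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger on the genome build GRCh38, per the submitters' processing notes, and the version was not given. The deposited matrices hold whole numbers for 33694 genes and for barcodes kept as cells, and the gene annotation and the use of strand in counting were not given in the sources used here. Gene IDs and symbols were taken as the files pair them. Coordinates are those of GENCODE release 29 on GRCh38, matched by gene ID for 33132 of the 33694 genes. No pair of libraries held the same cells with equal totals.

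Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 26, 15, 37 and 7 barcodes of BMPi replicates 1 and 2 and BMPa replicates 1 and 2. Doublets were scored with Scrublet in scanpy. Its own threshold marked at most 0.126% of the barcodes of a library and was not used. Instead the highest-scoring barcodes were removed up to an expected share of 0.8% per 1000 barcodes, which removed 32, 332, 20 and 218. The kept cells held 14378047, 76615243, 10089896 and 79443282 counts. Intervals for shares are 95% exact Clopper-Pearson intervals, limits for expression values of 0 are those of 3 counts, and both cover counting error only.

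Counts per cell were scaled to 10000 and log-transformed. Leiden clusters at resolution 1 were made from 2000 variable genes, 30 principal components and 15 neighbours, without correction between libraries. Clusters were named by 20 sets of marker genes, with at least 3 markers 2-fold above the other cells. A mean log2 score of 1 was required, but for neural progenitors, which made up most cells, this was lowered to 0.5 after the clusters had been seen. At a score of 1, 3 of the 11 progenitor-like clusters would have kept the name. Clusters 2, 15 and 23 stayed unnamed and held 11.9%, 12.9%, 13.0% and 12.1% of the cells of the libraries, BMPi before BMPa and replicate 1 before replicate 2. Neuron-like and intermediate-progenitor-like clusters were joined as the neuronal lineage. Classes rebuilt in this way can differ from those of the study.

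Counts were summed per library over all kept cells, and per class where each library had at least 30 cells of it, which left the neural-progenitor-like and neuronal classes. The sums were tested with edgeR's quasi-likelihood F test, with group as the sole term, TMM scaling and edgeR's filter on low counts, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The same edgeR test was used for the numbers of cells per class, with the kept cells as library size. An exact permutation test of 2 against 2 libraries cannot go below a p of 1 in 3 and was not used. Ratios within a replicate number are log2 ratios of TMM-scaled CPM after adding 1 and have no test. The other CPM values are counts over the sum's total.

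Lists of genes, 33 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, and also with an estimated correlation and with fry. The lists cover BMP, TGF-beta and activin, FGF, WNT, Notch, and VEGF and angiopoietin signalling. They cover the cortical hem and roof plate, dorsal and ventral telencephalon, diencephalon, and midbrain and hindbrain. For cell types they cover endothelial, mural, mesenchymal, basement membrane, blood-brain barrier, neural progenitor, neuron, synapse, choroid plexus, neural crest, retina and pigment, non-neural epithelium, muscle, pluripotency, and blood and microglia genes. For cell states they cover S phase, G2 and M phase, glycolysis and hypoxia, the unfolded protein and amino acid response, immediate early and heat shock genes, apoptosis and p53 targets, and the interferon response. A cell with at least 5 of 12 endothelial markers was counted as endothelial-like.

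The groups, tests, lists, markers, filters on cells, the rule for named genes and the alternatives were chosen before the data were examined. The settings of the clustering other than its resolution, the scores for naming clusters, the rule for endothelial-like cells and the joining of classes for shares were set later. Genes past the threshold were to be named by size of change. Where fewer than 5 passed in a direction, the rule named the 8 genes with the smallest p among those with at least 10 CPM in the higher group and both libraries of a group above both of the other. It also named members of each list by smallest p, up to 4, and 2 by highest CPM. For clusters it named the 5 genes with the largest fold over the other cells after adding 10 CPM, and other genes named from the leading 10 were chosen after they were seen. Genes called under other settings, the genes of the vascular search and the HOX and immediate early genes shown by replicate were chosen after their values were seen. Mitochondrial, ribosomal protein and clone-based genes were counted but not named.

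The methods were tested on simulated data. For the whole-library comparison, counts of 17207 genes were simulated with 200 changed, and edgeR found 1.5%, 52.2% and 98.5% of those changed by 2-fold, 4-fold and 16-fold, with 7 false calls of 108. For neural progenitors, with 15745 genes, it found 7.5%, 67.2% and 100%, with 16 false of 132, and for the neuronal class, with 13361 genes, 4.5%, 47.8% and 97%, with 22 false of 121. The false calls therefore exceeded 5% in each. In the simulation of lists on 17207 genes the list raised 2-fold ranked 1 and 0 other lists passed. Its genes were drawn independently, so it cannot show how camera's preset correlation fares when the genes of a list move together. It also used the smaller spread of a fit with the replicate number as a block. The simulations of genes above used the spread of the group-only fit. They drew the libraries independently, once each, whereas real libraries of the same number deviated together. They therefore do not show how many real changes were missed or falsely called. In 50 draws of class shares a 4-fold rise was found in 100%, but 15.3% of the other classes were called too, since shares add up to a whole, and with no change 1.71% were called. These draws had 3000 cells per library and a spread between libraries of 0.15 (SD of the natural log). Some real shares spread more, such as 3.77% and 0.360% of choroid-plexus-like cells in the BMPi libraries. The draws therefore do not show that a 4-fold rise would be found in these data. In simulated cells of 4 classes and 33694 genes the lowest share of cells with the right name was 100%.

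Alternatives were another scaling (DESeq2's size factors or total counts), DESeq2's test, no filter on low counts, other filters on cells and doublets, thinning to equal totals, equal weight to each class, other clusterings and class names, shares among neural cells, another form of the list test, a replicate block, and leaving out each library in turn. Where leaving out a library left 1 in a group, that library was assumed to vary like those of the other group. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.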

Results

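Single-cell RNA profiles were measured in vascularised brain organoids, which are small neural tissues grown in culture with a step meant to give vascular progenitors. They were made from H9, an established line of human embryonic stem cells, and were collected at day 32. The groups differed in the factors given for 2 days at the vascular step. The BMPi group received bFGF and VEGF together with SB431542, an inhibitor of the activin and TGF-beta type I receptors. The BMPa group received BMP4, a bone morphogenetic protein, in place of SB431542. Effects of BMP4 and of the lack of SB431542 can therefore not be told apart in this design. Each group had 2 independent replicates, which gave 4 libraries. For each of them 10000 to 12000 cells were loaded, per the labels.

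The deposited files held 1993 barcodes and 14845504 UMI counts for BMPi replicate 1, and 6446 barcodes and 84070507 counts for BMPi replicate 2. They held 1584 barcodes and 10339338 counts for BMPa replicate 1, and 5216 barcodes and 85715851 counts for BMPa replicate 2. After filtering, 1935, 6103, 1527 and 4992 cells were kept, in the same order, with medians of 6352, 10905, 5578 and 13359.5 counts per cell. Both libraries with replicate number 1 were therefore shallower and had fewer cells than both with number 2. For this reason BMPa over BMPi ratios within replicate 1 and within replicate 2 are given beside the pooled values. Levels are given in CPM, which is 1000 times a gene's counts per 1000 counts of the same sum. In a whole-library sum, 3 counts correspond to 0.209, 0.0392, 0.297 and 0.0378 CPM in the same order, and this limit covers counting error only. The p-values for genes and shares measure differences against the spread between these libraries. Those of camera with its preset correlation compare the genes of a list with the other genes, and do not rest on that spread alone. With an estimated correlation camera is limited by the few libraries, so a list that fails there is not shown to be unchanged.

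The 14557 kept cells formed 24 clusters, and 21 of them were named by marker genes as 6 classes. Neural-progenitor-like cells, named by genes such as SOX2 and PTPRZ1, made up most of each library under a naming score that was lowered after the clusters had been seen. At the score of 1 used for the other classes, 0.931% and 29.8% of these cells in BMPi and 0.898% and 29.9% in BMPa would have kept the name, replicate 1 before replicate 2. Cells of the neuronal lineage lay in neuron-like clusters, such as cluster 4 with NHLH2, LAMP5 and STMN2 among its leading genes, and in intermediate-progenitor-like clusters, such as cluster 16 with NEUROG1 and NEUROG2. Choroid-plexus-like cells lay in clusters 14 and 24, which had TTR and TRPM3 among their leading genes, and TTR encodes transthyretin, the carrier protein that the choroid plexus secretes. Cluster 14 held at least 95.1% of the class in each library. It had 4 choroid plexus markers at 2-fold and a score of 1.27, against 8 and 3.07 in cluster 24. SOST and CYP1B1 led it, with the hem and roof plate genes RSPO3 and RSPO1 among its leading genes. Its TTR was at 841 CPM, against 8889 CPM in cluster 24. Roof-plate-like cells can therefore not be told apart from choroid-plexus-like cells in cluster 14. Neural-crest- and Schwann-like cells had SPP1 and ERBB3 among their leading genes, melanocyte- and pigment-epithelium-like cells had PMEL and MLANA, and mesenchymal-like cells COL1A1, BGN and COL3A1. Immediate early genes, including FOS, JUN and EGR1, were among the leading genes of the progenitor-like clusters 1 and 9. These clusters held 66.0% and 31.6% of the progenitor-like cells of BMPi replicate 1, and 69.0% and 28.7% of those of BMPa replicate 1. In both replicate 2 libraries they held at most 1.09% each. Clusters 2, 15 and 23 stayed unnamed.

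Within each group, replicate 1 and replicate 2 differed in genes of position along the body axis and of the early response to stimuli. In neural-progenitor-like cells HOXB4, a gene of hindbrain and spinal cord identity, had 10.9 CPM in BMPi replicate 1 and 2.08 CPM in BMPa replicate 1, and 77.1 and 63.6 CPM in the replicate 2 libraries. FOS, an immediate early gene that dissociation of tissue also induces, had 940 and 778 CPM in replicate 1 and 117 and 193 CPM in replicate 2, BMPi before BMPa. Over 7 HOX genes the median log2 ratio of replicate 1 over replicate 2 in these cells was -1.69 in BMPi and -2.41 in BMPa, with 0 of 7 higher in replicate 1 in either group. Over 12 immediate early and heat shock genes it was 2.41 in BMPi and 1.71 in BMPa. With 1 library per group and number these differences were not tested.

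**Figure D1:**
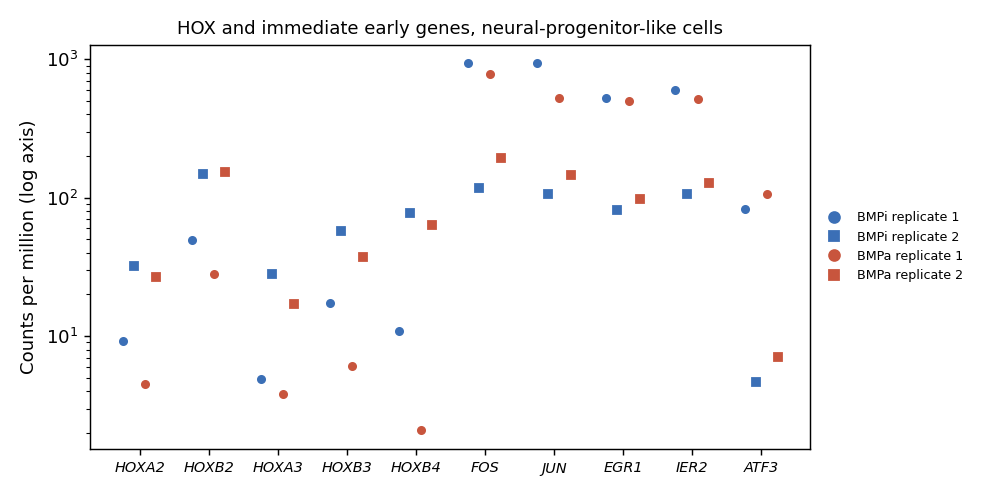
CPM (log axis) of 5 HOX genes and 5 immediate early genes in neural-progenitor-like cells of each library (blue, BMPi; red, BMPa; circles, replicate 1; squares, replicate 2). HOXB4 lies at 10.9 and 2.08 CPM in the replicate 1 libraries and at 77.1 and 63.6 CPM in the replicate 2 libraries, and FOS at 940 and 778 against 117 and 193 CPM.

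The share of each class was compared to ask whether BMP4 in place of SB431542 altered which cells the organoids contained. Neural-progenitor-like cells made up 67.7% ± 6.24 (SD, n = 2) of the BMPi libraries and 57.8% ± 0.847 (SD, n = 2) of the BMPa libraries. Choroid-plexus-like cells made up 2.07% ± 2.41 (SD, n = 2) in BMPi and 9.62% ± 11.1 (SD, n = 2) in BMPa. Their share was 3.77% in BMPi replicate 1 (95% exact Clopper-Pearson interval 2.97 to 4.72) and 17.5% in BMPa replicate 1 (15.6 to 19.5). In replicate 2 it was 0.360% in BMPi (0.226 to 0.545) and 1.76% in BMPa (1.42 to 2.17). The BMPa share was thus 4.63 times the BMPi share in replicate 1 and 4.89 times in replicate 2. In replicate 2 this ratio depended on how cells were grouped, and was 1.62 at resolution 0.5, 1.94 with the stricter filter on cells, 1.54 with thinned cells, 10.2 without removal of doublets and 0.972 with a marker score per cell, but 4.83 at resolution 2 and no lower with values centred per library. In replicate 1 it was 1.35 with a marker score per cell and from 4.19 to 4.68 in the other settings. Mesenchymal-like cells made up 1.14% ± 1.03 (SD, n = 2) in BMPi and 2.81% ± 1.85 (SD, n = 2) in BMPa, with ratios of 2.22 and 3.67 within the replicate numbers. The log2 ratio of the mesenchymal-like share was 1.32 over all libraries, ranged from 0.42 to 2.76 when each library was left out, and was 0.40 with the stricter filter on cells. At resolution 2 the ratios within replicates 1 and 2 were 2.01 and 1.53. They were 1.45 and 1.04 with the stricter filter on cells, and 1.22 and 1.24 with a marker score per cell.

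Neural-crest- and Schwann-like cells made up 1.34% ± 1.09 (SD, n = 2) in BMPi and 3.79% ± 4.53 (SD, n = 2) in BMPa, with ratios of 1.04 and 3.31 within the replicate numbers. Under other ways of grouping or filtering cells these ratios ranged from 1.08 to 2.01 in replicate 1 and from 1.74 to 3.75 in replicate 2. Cells of the neuronal lineage made up 13.7% ± 5.70 (SD, n = 2) and 12.3% ± 8.60 (SD, n = 2), with ratios of 0.644 and 1.04. Melanocyte- and pigment-epithelium-like cells made up 1.64% ± 2.17 (SD, n = 2) and 1.15% ± 1.35 (SD, n = 2), with ratios of 1.90 and 0.662, which ranged from 1.06 to 3.81 and from 0.594 to 1.17 under the same alternatives. Unnamed cells made up 12.4% ± 0.713 (SD, n = 2) and 12.6% ± 0.660 (SD, n = 2). In edgeR's quasi-likelihood test of the cell counts, the log2 ratio of the progenitor-like share was -0.23 ± 0.0858 (SE) with an adjusted p of 0.460. Among cells of the neural classes only it was -0.0028 with an adjusted p of 0.990 by edgeR. That of the choroid-plexus-like share was 2.23 ± 1.80 (SE) with an adjusted p of 0.759. When each cell was named by its highest marker score instead of by its cluster, the choroid-plexus-like ratio was 0.33 with an adjusted p of 0.867 by edgeR. The adjusted p of edgeR's test was 0.759 for the mesenchymal-like and the crest- and Schwann-like shares and 0.939 for the others, so no share passed the threshold of 0.05 with group as the sole term. With the replicate number as a block the choroid-plexus-like share passed, at a log2 ratio of 2.24 and an adjusted p of 0.00249 by edgeR. The labels do not state such a pairing. Without BMPi replicate 2 the progenitor-like share passed, at a log2 ratio of -0.32 and an adjusted p of 0.000730 by edgeR. The log2 ratio of the choroid-plexus-like share was -0.22 without BMPa replicate 1 and 4.72 without BMPi replicate 1, and neither of these ratios passed. The crest- and Schwann-like ratio was -1.19 without BMPa replicate 2, the melanocyte-like ratio 3.45 without BMPi replicate 2, and the neuronal ratio 0.35 without BMPi replicate 2 and 0.42 without BMPa replicate 1.

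**Figure D2:**
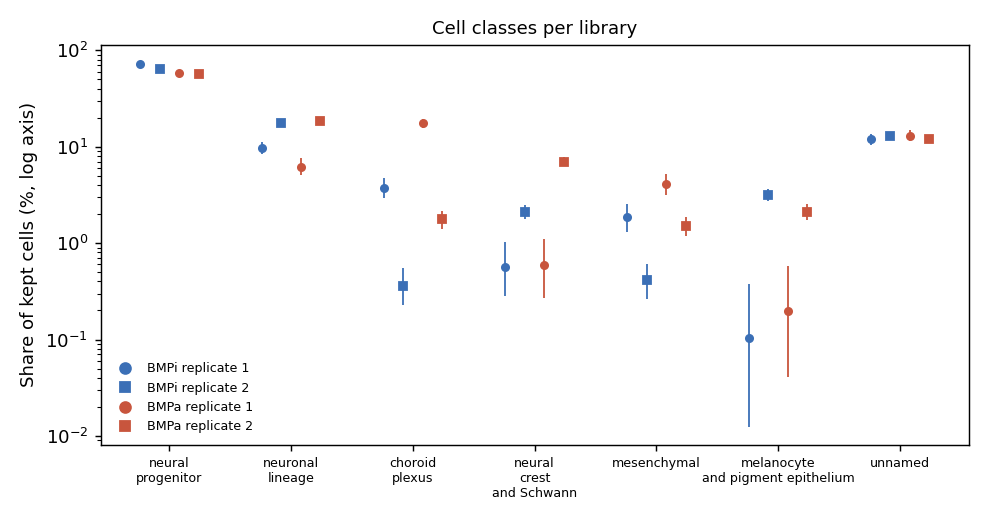
Share of each cell class among the kept cells of each library, in percent on a log axis, with 95% exact Clopper-Pearson intervals that cover counting error only (blue, BMPi; red, BMPa; circles, replicate 1; squares, replicate 2). Choroid-plexus-like cells lie at 3.77% and 0.360% in the BMPi libraries and at 17.5% and 1.76% in the BMPa libraries.

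Endothelial cells were looked for because the differing factors were given at the vascular step. A cell with at least 5 of 12 endothelial markers was found once in BMPi replicate 1, with 9 of the markers, and once in BMPa replicate 1, with 10. Both of these cells were in the mesenchymal-like class. None was found among the 6103 and 4992 cells of the replicate 2 libraries, for which the 95% exact Clopper-Pearson interval reaches 0.0604% in BMPi and 0.0739% in BMPa. Those libraries held 3 and 9 cells with 3 or 4 of the markers, and the replicate 1 libraries 0 and 2, so the numbers depend on the limit of 5. PECAM1, an adhesion molecule of endothelial cells, had 4 and 3 counts in the BMPi libraries and 4 and 2 in the BMPa libraries. KDR, the main receptor for VEGF, had 0.278 and 0.0131 CPM in BMPi and 2.08 and 0.0881 CPM in BMPa, replicate 1 before replicate 2, and its value in BMPi replicate 2 rests on 1 count. FLT1, another receptor for VEGF, went the other way, with 1.18 and 0.0261 CPM in BMPi and 0.694 and 0 CPM in BMPa, and its replicate 2 values rest on fewer than 3 counts. CLDN5, a tight junction protein of brain endothelium, had 9.95 and 7.32 CPM in BMPi and 53.8 and 12.5 CPM in BMPa, and within the neuronal class it had 24.3, 31.9, 71.3 and 48.8 CPM. Of the blood and microglia genes, AIF1 had 5.36 and 5.72 CPM in BMPi and 33.5 and 9.26 CPM in BMPa. That list was not tested, since fewer than 5 of its members were measured. Cluster 23, which had ATF3, DDIT3, CHAC1 and AIF1 among its leading genes, held 87 cells of BMPa replicate 1, 7 of BMPi replicate 1 and 1 of BMPa replicate 2.

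Expression summed over each whole library was compared to ask which genes and pathways differed after BMP4 in place of SB431542. Choroid plexus genes rose as a list in BMPa, with a median log2 ratio of 2.40 over 11 measured members, 10 of them positive. This call and the others in this paragraph hold for camera with its preset correlation, and with an estimated correlation 0 of 32 lists passed (adjusted p of camera 0.484 for choroid plexus genes). In this list TTR had 46.0 and 0.157 CPM in BMPi and 376 and 16.7 CPM in BMPa, replicate 1 before replicate 2. Genes of the cortical hem and roof plate, the dorsal midline of the neural tube, rose with a median of 0.87 and 12 of 12 members positive, among them RSPO3 at 1.40 ± 0.564 (SE) and LMX1A at 1.54 ± 0.730. BMP pathway targets rose with a median of 0.44 and 12 of 14 positive, among them BAMBI at 1.28 ± 0.537 and ID1 at 0.47 ± 0.335. Genes of G2 and M phase fell with a median of -0.39 and 0 of 22 positive, among them CENPF at -0.62 ± 0.245.

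Of 32 lists tested in whole-library sums with limma's camera and its preset correlation, 10 were higher and 4 lower in BMPa. The adjusted p was 8.89e-11 for the choroid plexus and the hem and roof plate lists, 2.68e-05 for BMP targets and 1.53e-11 for G2 and M phase. Non-neural epithelium genes, such as the keratin KRT19, had a median of 1.00 and an adjusted p of 2.25e-10, and mesenchymal and extracellular matrix genes a median of 0.51 and an adjusted p of 5.37e-09. The unfolded protein and amino acid response had a median of 0.50 (adjusted p = 0.000291), neural crest genes 0.55 (0.0138), mural genes 0.43 (0.00561), endothelial genes 0.26 (0.00750) and blood-brain barrier and junction genes 0.20 (0.00889). Of the endothelial list 10 of 19 genes were measured, and its member CLDN5 was also expressed in the neuronal class. With few endothelial-like cells found, the rise of this list does not show more endothelial cells. Midbrain and hindbrain genes had a median of -0.69 (adjusted p = 0.00674), neural progenitor genes -0.28 (0.00305) and S phase genes -0.22 (0.00305). With an estimated correlation 0 lists passed, and the adjusted p of camera was 0.612 for the mural, neural crest and S phase lists and 0.484 for the other 11. With that setting 2 lists had an unadjusted p under 0.05. In fry's test of movement in 1 direction 0 lists passed, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.827. In fry's test of change in either direction 0 lists passed, and its lowest adjusted p was 0.647.

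Within replicate 1 and replicate 2, the median log2 ratios were 1.77 and 0.23 for choroid plexus genes, 1.08 and 0.32 for hem and roof plate genes, and 0.57 and 0.32 for BMP targets. Unlike the fitted values, ratios within a replicate are taken after adding 1 CPM, which draws genes of low CPM towards 0. They were 0.72 and 0.57 for non-neural epithelium genes, 0.63 and 0.25 for mesenchymal genes, 0.58 and 0.10 for the unfolded protein response, and 0.24 and 0.66 for neural crest genes. They were 0.28 and 0.17 for mural genes, 0.17 and 0.068 for endothelial genes, and 0.59 and 0.017 for blood-brain barrier genes. They were -0.61 and -0.21 for G2 and M phase, -0.38 and -0.13 for S phase, -0.73 and -0.47 for midbrain and hindbrain genes, and -0.073 and -0.27 for neural progenitor genes. The camera calls for the choroid plexus, mesenchymal, non-neural epithelium and G2 and M phase lists held without each of the 4 libraries in turn. Without BMPa replicate 1, 6 lists were higher and 2 lower. The adjusted p of camera was then 0.164 for BMP targets, 0.178 for hem and roof plate, 0.681 for endothelial, 0.821 for mural, 0.673 for blood-brain barrier, 0.252 for neural progenitor and 0.355 for midbrain and hindbrain genes. For the unfolded protein response and S phase it was 0.940, with the direction turned. Without BMPi replicate 2 the adjusted p of camera was 0.585 for endothelial, 0.662 for mural, 0.116 for unfolded protein response, 0.622 for S phase and 0.254 for neural progenitor genes, and 0.923 with the direction turned for midbrain and hindbrain genes. The neural crest list turned direction without BMPi replicate 1 (adjusted p of camera 0.379) and without BMPa replicate 2 (0.0995). The blood-brain barrier call was also lost without BMPi replicate 1 (0.295) and with no filter on low counts (0.0732).

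**Figure D3:**
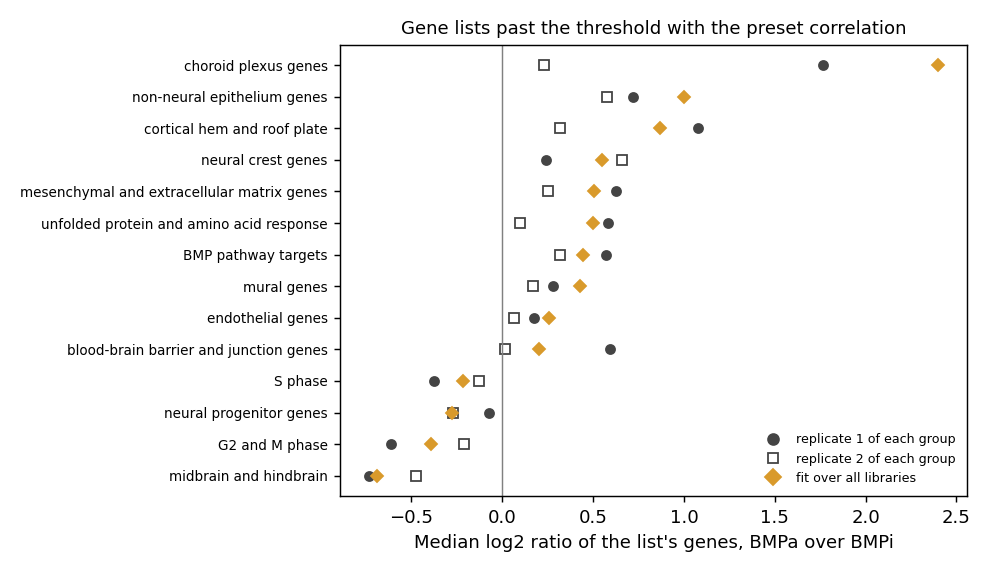
Median log2 ratio of BMPa over BMPi for the 14 lists that passed the camera test with the preset correlation in whole-library sums (diamonds, fit over all libraries; filled circles, replicate 1; open squares, replicate 2). Choroid plexus genes lie at 2.40 in the fit, at 1.77 in replicate 1 and at 0.23 in replicate 2, and G2 and M phase genes at -0.39, -0.61 and -0.21. The replicate values are ratios after adding 1 CPM, which draws genes of low CPM towards 0, and the fitted values are not.

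The other lists did not pass in whole-library sums, and the values given for each are the median log2 ratio and the adjusted p of camera with the preset correlation. For signalling they were 0.18 and 0.446 for TGF-beta and activin targets, 0.18 and 0.319 for FGF targets, 0.36 and 0.273 for WNT targets, -0.19 and 0.810 for the Notch pathway, and 0.24 and 0.280 for VEGF and angiopoietin signalling. For regions of the brain they were 0.068 and 0.985 for the dorsal telencephalon, -0.59 and 0.425 for the ventral telencephalon and GABA neurons, and -0.39 and 0.468 for the diencephalon. For cell types they were -0.043 and 0.299 for neuron genes, -0.045 and 0.752 for synapse genes, -0.41 and 0.684 for retina and pigment genes, 0.19 and 0.0577 for muscle genes, and -0.19 and 0.182 for pluripotency genes. For the remainder they were 0.31 and 0.185 for the basement membrane, 0.12 and 0.280 for glycolysis and hypoxia, -0.18 and 0.524 for immediate early and heat shock genes, 0.078 and 0.320 for apoptosis and p53 targets, and 0.081 and 0.320 for the interferon response. The mean and the median differed in sign for the Notch pathway (mean 0.021, test upward), the ventral telencephalon (0.065, downward), the diencephalon (0.34, downward) and synapse genes (0.092, downward).

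Among single genes in whole-library sums, those that both BMPa libraries expressed above both BMPi libraries included MFAP4, an extracellular matrix glycoprotein, at 6.54 ± 1.09 CPM in BMPi and 21.3 ± 3.36 CPM in BMPa (SD, n = 2). Its log2 ratio was 1.62 ± 0.300 (SE), with 1.82 and 1.19 within replicates 1 and 2. COL1A1, which encodes a chain of type I collagen and lies on chromosome 17 at 50183289 to 50201632 of GRCh38, had 10.6 ± 4.50 and 39.0 ± 7.70 CPM (SD, n = 2) and a log2 ratio of 1.83 ± 0.369 (SE). PPP1R14C, an inhibitor of protein phosphatase 1, had a ratio of 1.28 ± 0.251, and MSX2, a transcription factor induced by BMP signalling, 0.85 ± 0.250. COL1A2, ASS1, S100A11 and PLP2 had ratios of 0.92, 1.22, 1.09 and 1.46. PAX6, a transcription factor of neural progenitors on chromosome 11 at 31784779 to 31818062, had 33.8 ± 10.2 CPM in BMPi and 10.0 ± 1.02 CPM in BMPa (SD, n = 2). Its log2 ratio was -1.80 ± 0.307 (SE), with -2.07 and -1.31 within replicates 1 and 2. FRZB, a secreted WNT inhibitor, had a ratio of -1.18 ± 0.258, SCUBE2, a secreted protein that helps to release hedgehog ligands, -1.58 ± 0.386, and WNT7A, a WNT ligand, -1.01 ± 0.285. MLLT3, RGS20, PHYHIPL and ENPP2 had ratios of -1.22, -0.98, -0.88 and -0.99. These 16 genes had the smallest p in each direction and did not pass with group as the sole term. In edgeR's quasi-likelihood test 0 of 17207 genes were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 1.00. At an unadjusted p under 0.05 there were 172 genes, where 860 were expected by chance, and DESeq2 also called 0. With fewer small p-values than expected by chance, the lack of calls does not show that genes were unchanged. With the replicate number as a block edgeR called 84 genes higher and 53 lower. Of the 16 genes named above, all but PLP2 (adjusted p = 0.343) then passed, such as COL1A1 (0.000297) and PAX6 (0.00182). Such a pairing is not stated in the labels. With group as the sole term, 0 members of the lists passed over all genes. In that fit, adjusted over the list alone, PAX6 passed in the dorsal telencephalon and the neural progenitor lists and KRT19 in the non-neural epithelium list.

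**Figure D4:**
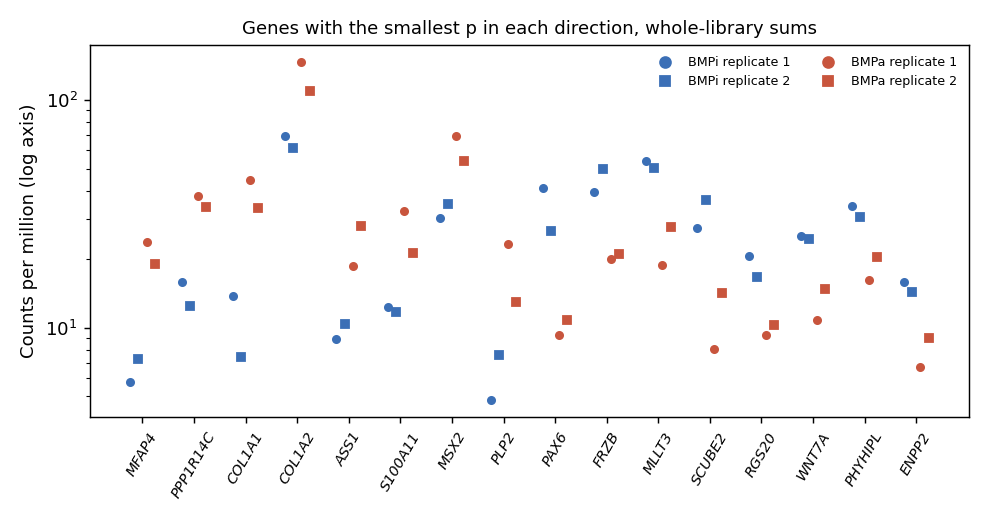
CPM (log axis) of the 16 genes with the smallest p in each direction in whole-library sums, for each library (blue, BMPi; red, BMPa; circles, replicate 1; squares, replicate 2). PAX6 averages 33.8 CPM in BMPi and 10.0 CPM in BMPa, and COL1A1 10.6 and 39.0 CPM, and none of the genes passed the test over all genes with group as the sole term.

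Within neural-progenitor-like cells the comparison asked what differed apart from the mix of classes. BMP pathway targets rose as a list in BMPa, with a median log2 ratio of 0.62 over 13 members, 12 of them positive, and medians of 0.70 and 0.46 within replicates 1 and 2. The adjusted p of camera for this list was 1.71e-09 with the preset correlation and 0.604 with an estimated correlation. Among them ID1, an inhibitor of neuronal differentiation factors, had 885 ± 233 CPM in BMPi and 1451 ± 174 CPM in BMPa (SD, n = 2) and a log2 ratio of 0.66 ± 0.242 (SE). ID3 had a ratio of 0.65 ± 0.266, MSX2 0.96 ± 0.274 and ATOH8 1.03 ± 0.294. Of the BMP targets, ID1, ID2, ID4 and MSX2 were also among the leading genes of the progenitor-like cluster 13. That cluster held 1.86% of these cells in BMPi replicate 2 and 14.2% in BMPa replicate 2, but 0% and 0.337% in replicate 1. In replicate 2 a shift between clusters of the class can therefore not be told apart from a rise within cells. The call with the preset correlation held without each of the 4 libraries in turn.

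The hem and roof plate list also rose in neural-progenitor-like cells (median 0.35, adjusted p of camera 0.000533 with the preset and 0.645 with an estimated correlation), with RSPO1, a secreted enhancer of WNT signalling, at 0.98 ± 0.276 (SE). Further lists that rose with the preset correlation alone were non-neural epithelium genes (median 0.32, adjusted p = 0.00209), muscle genes (0.58, 0.00237), the unfolded protein response (0.32, 0.000536) and blood-brain barrier genes (0.19, 0.0431). G2 and M phase genes fell (median -0.21, adjusted p = 0.000494), with 0 of 22 positive. With an estimated correlation 0 of 30 lists passed, with 1 at an unadjusted p under 0.05, and the adjusted p of camera was 0.826 for G2 and M phase and 0.645 for the lists that rose other than BMP targets. In fry's test of movement in 1 direction 0 passed, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.581. Within replicates 1 and 2 the medians were 0.52 and 0.14 for hem and roof plate, 0.45 and 0.35 for epithelium, 0.080 and 0.15 for muscle, 0.31 and 0.15 for unfolded protein response, 0.28 and 0.060 for blood-brain barrier and -0.48 and -0.032 for G2 and M phase genes. The G2 and M phase call was lost without BMPi replicate 2 (adjusted p of camera 0.225) and turned direction without BMPa replicate 1 (0.688). The unfolded protein response call was lost without BMPi replicate 2 (0.510) and turned direction without BMPa replicate 1 (0.469). Without BMPi replicate 1 the adjusted p was 0.390 for the hem and roof plate and blood-brain barrier lists and 0.424 for epithelium. Without BMPa replicate 1 the blood-brain barrier list had an adjusted p of 0.931, and without BMPi replicate 2 it was 0.113. Without BMPi replicate 2, 3 lists were higher, and 3, 2 and 4 were lower without BMPi replicate 1, BMPi replicate 2 and BMPa replicate 2. With no filter on low counts the adjusted p was 0.346 for blood-brain barrier and 0.131 for epithelium genes. The other 23 lists had an adjusted p of camera from 0.0806 to 0.982 with the preset correlation. Median, mean and test differed in sign for the mesenchymal list (median -0.087, mean 0.044, upward), the diencephalon (-0.037, 0.26, upward), the Notch pathway (-0.070, 0.015, upward), neural crest (-0.065, 0.069, downward) and retina genes (-0.058, 0.054, upward).

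Single genes of neural-progenitor-like cells that were higher in both BMPa libraries included PPP1R14C, at 15.4 ± 3.17 CPM in BMPi and 51.5 ± 5.04 CPM in BMPa (SD, n = 2), with a log2 ratio of 1.69 ± 0.266 (SE). HLA-DRB1, SAMD11, DIO3 and APOE had ratios of 1.76, 1.42, 0.77 and 0.88, and HLA-DRB1 shares sequence with other HLA-DRB genes, so its counts are uncertain. PAX6 had 37.6 ± 14.3 CPM in BMPi and 11.7 ± 2.70 CPM in BMPa (SD, n = 2), with a log2 ratio of -1.72 ± 0.367 (SE), and -2.20 and -1.04 within replicates 1 and 2. PAX3, a transcription factor of the dorsal neural tube, had a ratio of -0.72 ± 0.216, FRZB -1.42 ± 0.405 and SCUBE2 -1.31 ± 0.375. PHYHIPL, SPARCL1, MEGF10 and S100A16 had ratios of -0.86, -1.26, -0.88 and -1.06. In edgeR's test 0 of 15745 genes were higher and 0 lower, with 90 at an unadjusted p under 0.05, where 787 were expected by chance. With the replicate number as a block edgeR called 33 higher and 50 lower. Of the genes named here PPP1R14C (adjusted p = 0.00013), PAX6 (0.0187) and FRZB (0.000865) were among these. DIO3, APOE, SPARCL1 and MEGF10 were not. DESeq2 called 1 gene, PPP1R14C, with an adjusted p of 0.0308. With no filter on low counts edgeR called 7 genes higher, PPP1R14C among them (adjusted p = 0.00609), and 13 lower, among them PAX6 (0.00636) and FRZB (0.0430). The HOX genes HOXA7, HOXA9, HOXC9 and HOXC10 were also among the 13 lower genes. With group as the sole term and the filter on low counts, 0 list members passed over all genes. Adjusted over the list alone, PAX6 then passed in the dorsal telencephalon list. The progenitor-like cells of replicate 1 lay mainly in clusters 1 and 9 and those of replicate 2 in other clusters. In BMPa replicate 2, 14.2% of them lay in cluster 13, whose leading genes included PPP1R14C and the BMP targets ID1 and MSX2, against 1.86% in BMPi replicate 2. Cluster 6, with PAX6 and FRZB among its leading genes, held 7.71% and 18.5%.

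Within cells of the neuronal lineage the same question was asked of neurons and their immediate precursors. Neural crest genes rose as a list in BMPa, with a median log2 ratio of 1.03 and 8 of 11 members positive, among them ERBB3, a receptor for neuregulin, at 3.18 ± 0.802 (SE). As in the other comparisons, this call and those that follow hold for the preset correlation alone. With an estimated correlation, where few libraries limit the test, 0 of 27 lists passed. Muscle genes rose with a median of 1.62 and 3 of 5 positive, among them CHRNA1, a subunit of the acetylcholine receptor, at 2.12 ± 0.641. G2 and M phase genes rose with a median of 0.71 and 22 of 22 positive, and blood-brain barrier and junction genes with a median of 0.59 and 6 of 8 positive, among them CLDN5 at 1.01 ± 0.369. Midbrain and hindbrain genes fell with a median of -0.72 and 1 of 11 positive, among them PAX2, a transcription factor of the midbrain-hindbrain boundary and of spinal interneurons, at -2.53 ± 0.669. ERBB3, CHRNA1 and PAX2 rest on few counts in a library of replicate 1, which had 187 and 95 cells of this class. There they had 0, 0.935 and 17.8 CPM in BMPi and 5.94, 11.9 and 0 CPM in BMPa.

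The adjusted p of camera in cells of the neuronal lineage was 0.000327 for neural crest, 0.00588 for muscle, 4.03e-05 for G2 and M phase, 0.000716 for blood-brain barrier and 0.00634 for midbrain and hindbrain genes. With an estimated correlation 0 of 27 lists passed and 0 had an unadjusted p under 0.05, and the adjusted p of camera was 0.749 for neural crest and G2 and M phase genes and 0.692 for the other 3. In fry's test of movement in 1 direction 0 lists passed, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.375. Within replicates 1 and 2 the medians were -0.20 and 0.90 for neural crest, 0.083 and 0.62 for G2 and M phase, 0.066 and 1.20 for muscle, 0.98 and 0.17 for blood-brain barrier and -1.18 and -0.81 for midbrain and hindbrain genes. The neural crest call turned direction without BMPa replicate 2 (adjusted p of camera 0.227). G2 and M phase turned direction without BMPa replicate 2 (0.178) and was lost without BMPi replicate 1 (0.611). Blood-brain barrier genes were lost without BMPa replicate 1 (0.107) and without BMPi replicate 1 (0.328). Midbrain and hindbrain genes were lost without BMPa replicate 1 (0.491) and turned direction without BMPi replicate 2 (0.792). Without BMPa replicate 2, 2 lists were higher, while 5 were lower without BMPi replicate 1 and 3 without each of the other libraries. The other 22 lists had an adjusted p of camera from 0.0612 to 0.716. Median, mean and test differed in sign for endothelial genes (median -0.015, mean 0.15, upward) and glycolysis (0.051, 0.0044, downward).

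Single genes of the neuronal lineage that were lower in both BMPa libraries included LAMP5, at 174 ± 23.5 CPM in BMPi and 47.9 ± 23.0 CPM in BMPa (SD, n = 2), with a log2 ratio of -1.79 ± 0.391 (SE). LHX1 and LHX5, transcription factors of inhibitory interneurons of the dorsal spinal cord and hindbrain, had ratios of -1.95 ± 0.467 and -1.59 ± 0.384. LHX5-AS1, whose span on chromosome 12 from 113472003 overlaps the start of the minus-strand gene LHX5 at 113472280, had a ratio of -2.06, and whether the counting used strand was not given. SLIT1 and PAX6 had ratios of -1.39 and -1.78. NTN5, KIF19, PREX1, MFAP4, PAPPA2 and LGI2 were higher in both BMPa libraries, with ratios of 2.87, 1.65, 1.87, 1.28, 1.88 and 2.06. LGI2 rests on few counts in replicate 1, at 3.74 CPM in BMPi and 5.94 CPM in BMPa. In edgeR's test 0 of 13361 genes were higher and 0 lower, with 120 at an unadjusted p under 0.05, where 668 were expected by chance, and DESeq2 called 0. With the replicate number as a block edgeR called 77 higher and 61 lower. Each of the genes named above in this paragraph then passed, such as LAMP5 (adjusted p = 8.63e-11) and PAX6 (0.00513). With no filter on low counts edgeR called SPARCL1 higher, and LAMP5 and LHX5-AS1 lower, each with an adjusted p of 0.0371. Without BMPi replicate 1 it called 3 higher (PTH2, SLC17A6 and FOS) and 3 lower (LAMP5, PCP4 and HOXA9), with an adjusted p of 0.0247 for LAMP5. With group as the sole term, all libraries and the filter on low counts, 0 list members passed over all genes. Adjusted over the list alone, LHX5 then passed in the diencephalon list and ERBB3 in the neural crest list. Cluster 4, with LAMP5 among its leading genes, held 73.3% and 52.7% of the neuronal cells of the BMPi libraries and 50.5% and 31.4% of those of the BMPa libraries. Cluster 18, led by LHX9 and INSM1, held 22.5% and 1.76% against 48.4% and 21.9%, and cluster 17, led by PPP1R17 and RGS10, 3.21% and 5.73% against 1.05% and 26.1%.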

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

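Of the tests in this part, the one on doublets was chosen only after the result it measures was seen, and the one on the mix of clusters after the pattern but before its own value. Each of the 3 results below was picked out because the log2 ratio of BMPa over BMPi went opposite ways in the neural-progenitor-like and the neuronal classes, in both replicate numbers, and the difference between the classes was not tested.

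BMP pathway targets had a median log2 ratio of 0.62 in neural-progenitor-like cells and -0.12 in the neuronal class, where the median of replicate 1 was -0.023, and 0 after thinning to equal totals. Cortical hem and roof plate genes had medians of 0.35 in neural-progenitor-like cells and -0.40 in the neuronal class.

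G2 and M phase genes had a median log2 ratio of -0.21 in neural-progenitor-like cells and 0.71 in the neuronal class, but in progenitor sums of replicate 2 the median was -0.032, and thinning to equal totals turned it to 0.045, which ended the opposite signs there. If doublets of neurons with progenitors raised progenitor genes as much in the neuronal class, those genes would be higher there. The 15 neural progenitor genes had a median of -0.39 in this class (SD 0.62 over the genes). That does not exclude doublets, since the mix of clusters may lower these genes as well. In replicate 2 the intermediate-progenitor-like clusters 16 and 20 held 25.4% and 14.4% of the class in BMPi and 12.6% and 7.95% in BMPa. The mix of clusters may contribute, since within cluster 4 the mean over the replicate numbers of the list's median was 0.082, against 0.36 in the whole class. That cannot be told apart from noise, as 21 of the 22 members had fewer than 3 counts in a library of that cluster. An effect of BMP4, or of the lack of SB431542, on cycling in each class stays open as well and was not tested.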

How the results depend on the processing

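The alternative that joined classes was chosen only after the data were seen, and the others before. Of 1625 values under alternatives, 167 of those that answer a comparison and 1125 of the others kept their direction and their side of the threshold. Of those that answer a comparison 16 were weaker, 27 stronger and 11 turned direction, and of the others 79 were weaker, 96 stronger and 104 turned, and of all sign changes 95 were between values past no threshold. The cause of the changes below was not tested, except that the fits without a library have fewer samples and those with no filter more genes.

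With an estimated correlation and with fry, 0 lists were higher and 0 lower in whole-library sums, in neural-progenitor-like cells and in the neuronal class. With no filter on low counts edgeR called 7 genes higher and 13 lower in neural-progenitor-like cells and 1 higher and 2 lower in the neuronal class, where 5 lists were lower. DESeq2 called 1 gene higher in neural-progenitor-like cells. With total counts 2 lists were lower in these cells. The log2 ratio of the melanocyte-like share was 0.15 with a marker score per cell, and that of the choroid-plexus-like share 0.33. The ratio of the neuronal share was 0.018 and that of the progenitor-like share -0.0028 among neural classes, and that of unnamed cells -0.22 at resolution 0.5. With no filter the direction turned in whole-library sums for Notch (adjusted p of camera 0.992), ventral telencephalon (0.721) and retina genes (0.992). It also turned for mural, dorsal telencephalon and pluripotency genes (0.939 each) and interferon response (0.771) in neural-progenitor-like cells, and for interferon response (0.944) in the neuronal class. With total counts it turned for the dorsal telencephalon in whole-library sums (0.956), and for the dorsal telencephalon and diencephalon in neural-progenitor-like cells (0.962 each).

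Replicate numbers were not taken as a pairing, since there are 2 pairs and the labels give no batch. Libraries of the same number deviated together, with correlations of 0.669, 0.708 and 0.419 in whole-library, neural-progenitor-like and neuronal sums. With the number as a block, edgeR called 84 genes higher and 53 lower in whole-library sums, 33 and 50 in neural-progenitor-like cells and 77 and 61 in the neuronal class. The log2 ratio of the choroid-plexus-like share was 2.24 with the block (adjusted p of edgeR 0.00249), and 2.23 with the block and classes joined (2.52e-05), where the joined crest, melanocyte and mesenchymal share also passed (0.91, adjusted p of edgeR 0.00103). With the block 2 lists were lower in neural-progenitor-like cells and 3 in the neuronal class with the preset correlation. With an estimated correlation 0 lists passed under the block, and the lowest adjusted p of camera was 0.576 in whole-library sums, 0.864 in neural-progenitor-like cells and 0.731 in the neuronal class. BMP targets in whole-library sums then had an estimated correlation of 0.011, near the preset 0.01. Their adjusted p of camera was 1.81e-07 with the preset and 0.576 with the estimate, so that call was not lost through the correlation. The block turned the direction of the Notch list (adjusted p of camera 0.839) and of the dorsal telencephalon, diencephalon and immediate early lists (0.629 each) in whole-library sums, and of the dorsal telencephalon and immediate early lists in neural-progenitor-like cells (0.729 each).

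Leaving out each library in turn gave 0 to 3 genes higher and 0 to 3 lower in the neuronal class. The log2 ratio ranged from -0.22 to 4.72 for the choroid-plexus-like share, -3.05 to 3.45 for the melanocyte-like, -1.19 to 2.74 for the crest- and Schwann-like, 0.42 to 2.76 for the mesenchymal-like, -0.32 to -0.13 for the progenitor-like, -1.14 to 0.42 for the neuronal and -0.037 to 0.080 for the unnamed share. In whole-library sums 6 to 13 lists were higher and 2 to 5 lower, in neural-progenitor-like cells 3 to 8 and 1 to 4, and in the neuronal class 2 to 5 and 3 to 5. The ranges that follow belong to lists whose direction turned without a library. In whole-library sums camera's adjusted p ranged from 0.151 to 0.940 for TGF-beta and activin targets, 0.00389 to 0.940 for FGF pathway targets, 0.0799 to 0.769 for WNT pathway targets, 0.254 to 0.993 for Notch pathway and 0.151 to 0.940 for VEGF and angiopoietin signalling. The range in these sums was 0.0433 to 0.977 for basement membrane, 0.174 to 0.951 for dorsal telencephalon, 0.0256 to 0.804 for ventral telencephalon, 0.379 to 0.940 for diencephalon and 1.66e-05 to 0.923 for midbrain and hindbrain. For further lists it went from 7.57e-07 to 0.536 for neuron genes, 1.1e-11 to 0.379 for neural crest genes, 6.92e-07 to 0.635 for retina and pigment genes, 0.000281 to 0.635 for muscle genes and 0.503 to 0.635 for pluripotency genes. It also spanned 0.000195 to 0.940 for S phase, 0.00118 to 0.317 for glycolysis and hypoxia, 7.57e-07 to 0.940 for unfolded protein response, 5.85e-07 to 0.209 for immediate early and heat shock genes and 0.247 to 0.940 for interferon response. The range left was 0.103 to 0.883 for synapse genes. In neural-progenitor-like cells the adjusted p of camera ranged from 0.0388 to 0.628 for TGF-beta and activin targets, 0.0282 to 0.945 for FGF pathway targets, 0.0388 to 0.983 for WNT pathway targets and 0.225 to 0.983 for Notch pathway. Other ranges in these cells were 0.225 to 0.913 for mural genes, 0.0596 to 0.945 for mesenchymal and extracellular matrix genes, 0.165 to 0.913 for basement membrane and 0.360 to 0.692 for dorsal telencephalon. It further spanned 0.113 to 0.983 for neural progenitor genes, 0.0550 to 0.983 for neuron genes, 0.0148 to 0.983 for neural crest genes and 0.414 to 0.548 for pluripotency genes. Then came 0.0136 to 0.225 for S phase, 2.08e-06 to 0.688 for G2 and M phase, 0.00263 to 0.483 for glycolysis and hypoxia and 3.5e-09 to 0.510 for unfolded protein response. The rest spanned 8.27e-09 to 0.0700 for immediate early and heat shock genes, 0.280 to 0.983 for apoptosis and p53 targets, 0.826 to 0.983 for interferon response and 0.172 to 0.983 for synapse genes. In the neuronal class the adjusted p of camera ranged from 0.107 to 0.813 for BMP pathway targets, 0.359 to 0.931 for WNT pathway targets, 0.000563 to 0.440 for Notch pathway and 0.180 to 0.683 for VEGF and angiopoietin signalling. In the same class it spanned 5.33e-05 to 0.227 for mesenchymal and extracellular matrix genes, 1.26e-07 to 0.792 for midbrain and hindbrain, 1.41e-08 to 0.491 for neural progenitor genes and 2.66e-06 to 0.199 for neuron genes. Its range was also 9.26e-15 to 0.227 for neural crest genes, 0.00102 to 0.454 for S phase, 8.67e-21 to 0.611 for G2 and M phase and 0.00851 to 0.138 for glycolysis and hypoxia. Finally it was 0.0127 to 0.842 for unfolded protein response, 2.59e-09 to 0.475 for immediate early and heat shock genes, 0.197 to 0.825 for interferon response and 0.000917 to 0.326 for synapse genes. Without either replicate 2 library too few members were measured for a test of the epithelium, muscle, pluripotency and retina lists of neural-progenitor-like cells. The same held for the FGF, TGF-beta, basement membrane, dorsal telencephalon, endothelial, mural and muscle lists of the neuronal class, for its WNT list without BMPi replicate 2, and for pluripotency genes of whole-library sums without BMPa replicate 2.

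Depth limits the replicate 1 libraries most, where 3 counts are 0.209 and 0.297 CPM in whole-library sums. In class sums, which hold fewer counts, these limits are higher. The neuronal class had 187 cells in BMPi replicate 1 and 95 in BMPa replicate 1. Some settings gave no value for the melanocyte-like or mesenchymal-like share, since no cluster took that name.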

Other observations

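All tests of explanations in this part were chosen only after the results were seen.

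Clusters of the neuronal lineage differed in their leading genes. Cluster 18, named neuron-like, and cluster 20, named intermediate-progenitor-like, had ATOH1, BARHL1 and INSM1 among them, and ATOH1 and BARHL1 mark precursors of the rhombic lip and the most dorsal interneurons. Cluster 17, named intermediate-progenitor-like, had ISL1, POU4F1 and TLX3, transcription factors shared by sensory neurons, and NEUROD1 and SST. Cluster 24, of 17 choroid-plexus-like cells, had the cilium genes PIFO, RSPH1 and CFAP126 beside TTR, and 13 of these cells came from BMPa replicate 1. Cluster 11, of progenitor-like cells, was led by STC2, SLC16A3 and ALDOC, which hypoxia induces.

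HOXB2, which marks the hindbrain, had 47.4 and 160 CPM in BMPi and 22.0 and 151 CPM in BMPa, replicate 1 before replicate 2. SOST, a secreted inhibitor of WNT signalling that led both the choroid-plexus-like cluster 14 and the progenitor-like cluster 22, had 106 and 36.9 CPM in BMPi and 465 and 91.2 CPM in BMPa. HEY2, a target of Notch signalling, had 1.25 and 1.34 CPM in BMPi and 4.06 and 4.19 CPM in BMPa, with a log2 ratio of 1.60 ± 0.376 (SE) that did not pass over all genes.

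HOX genes were lower in the replicate 1 than in the replicate 2 libraries of both groups. In whole-library sums the 7 genes were also lower in BMPa than in BMPi within each number. HOXB4 had 9.74 and 1.49 CPM in replicate 1 and 69.3 and 52.4 CPM in replicate 2, BMPi before BMPa. In neural-progenitor-like cells of replicate 2 HOXB2 was not lower, at 148 and 154 CPM. The mix between cell classes does not account for the difference between replicates. Within neural-progenitor-like cells the median log2 ratio of replicate 1 over replicate 2 was -1.69 in BMPi and -2.41 in BMPa. Yet clusters 1 and 9 held 66.0% and 31.6% of these cells in BMPi replicate 1 and 69.0% and 28.7% in BMPa replicate 1. In the replicate 2 libraries they held at most 1.09% each. The class thus sets different clusters against each other, and a different mix of cells within it is not excluded. The depth of the libraries does not account for the lower HOX values, since genes matched on abundance lay 1.71 and 2.35 above the HOX median in sums thinned to equal totals. A difference between culture or library batches stays open, since the labels give no day or batch, and the leading principal component of progenitor sums (72.5% of the variance) restates that the numbers differ and would do so under any cause. For the same reason it gives a batch no support, and no biological explanation was tested.

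Choroid plexus genes were higher in BMPa than in BMPi libraries. The depth of the libraries does not account for this in replicate 1, where 9 members with at least 10 counts lay 2.10 above genes matched on abundance in thinned sums, whose median was 0.031, while in replicate 2 the gap over 6 members was 0.29 and excludes nothing. More choroid-plexus-like cells may account for part of it, but within that class the mean over the replicate numbers of the list's median log2 ratio was 1.33, against 1.03 over all kept cells. More cells and more expression per cell cannot be told apart, since 9 of the 11 members had fewer than 3 counts in a library of the class, and leaving the class out (0.18) settles nothing because these genes define it. An effect of BMP4 given at the vascular step, or of the lack of SB431542 there, remains open and untested against these.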
